A study of Rattus norvegicus with 28 samples.

How the data were processed

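Gene expression was measured by RNA sequencing in 28 libraries labelled as rat neural progenitor cells, in 7 groups of 4. One group was kept under culture conditions. The other 6 groups were exposed to spinal cord, either uninjured or injured, and carry a label of 2, 3 or 4 weeks. The groups called uninjured are labelled only as spinal cord, without mention of injury, and were read as uninjured. The study's title and design line concern the transplantation of neural progenitor cells into injured spinal cord in rodents. The labels do not say how each exposure was made, from which event the weeks are counted, whether the cells were separated from surrounding tissue, or whether samples of a group came from separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical. Replicate numbers follow the order of deposition and pair no samples.

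Per the labels' protocols, RNA was extracted with Trizol, treated with DNase on a column, cleaned with an RNeasy micro kit and made into libraries with a strand-specific total RNA kit for very small inputs. The submitters' processing notes list FastQC 0.11.5, Trim Galore 0.4.1, STAR 2.5.1, StringTie 1.3.3, featureCounts 1.5.1 and Picard, without their roles. The same notes name the build GRCm38, which is a mouse build, while the organism label is rat and the gene identifiers in the deposited table are rat Ensembl identifiers. Which genome the reads were aligned to is thus not settled by the sources used here. The annotation release, the strand setting and the handling of duplicate reads and of reads shared between similar genes are not given in the sources used here, so the counts of genes with near-identical copies or overlapping neighbours are uncertain.

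The authors deposited 1 table of raw counts per gene, with no normalization and 1 column for each library. It holds 32545 genes, of which 6584 had 0 counts in every library. Library totals ran from 84532 to 6908508 counts. The 8 week 2 libraries held at most 446331 counts and the other 20 at least 2605188, so that week 2 and low depth coincide. Counts without molecular identifiers are not independent molecules, and floors given for counts of 0 cover counting error only.

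The files do not pair the identifiers with gene symbols, and 0 of the 32545 identifiers matched the table of gene names used here. The 41 gene lists chosen before the data were examined, their tests, the 14 genes that were to be named whatever their result, and the alternative without mitochondrial and ribosomal RNA genes were therefore not run. The rule for naming genes asked for an adjusted p under 0.05, a mean log2 CPM of at least 2 over the libraries compared, no overlap between the libraries of the groups compared and a gene symbol, and took those with the largest log2 fold changes each way. It was applied without the symbol, and 2 identifiers that rose and 2 that fell are printed. The choice to print those of injured against uninjured at week 4 was made after the data were seen.

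Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust fit, TMM factors, filterByExpr by group) on the deposited counts. All 28 libraries entered 1 fit with a mean for each of the 7 groups and 21 residual degrees of freedom. The filter kept 13865 genes. Adjusted p-values are Benjamini-Hochberg values over those genes, and a gene was called at an adjusted p under 0.05. The fit gave 17 comparisons, fixed before the data were examined. They were injured against uninjured at each week, averaged over weeks and tested for a difference between weeks, exposed groups against culture, week 4 against week 2, and the 3 weeks within each condition. CPM values use TMM-scaled library sizes. Principal components and Spearman correlations between libraries used log2 CPM with a prior count of 2.

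Libraries were compared within groups before averaging. No pair of the 42 was identical, and their counts differed by more than sampling noise, with chi-square values per degree of freedom of 2.80 to 192. One library, injured week 3 replicate 3, had 0 counts for 2755 of the 9636 genes for which each other library of its group predicted at least 20. No other library had more than 3 such genes. It stayed in the fit as fixed, and each comparison is also given without it, from 14282 genes. Its presence raised the common dispersion from 0.0754 to 0.207, a biological coefficient of variation of 27.5% and 45.5%.

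Alternatives chosen before the data were examined were RLE and upper quartile factors, DESeq2 1.42.0, limma 3.58.1 (voom with library quality weights), no low count filter, a filter of at least 1 CPM in at least 4 libraries (15782 genes, more than filterByExpr kept), the log2 library total as a covariate, a test against a fold change of 1.5, fits of the compared groups only, and leaving out each library in turn. Left-out sets of more than 1 library, RLE and voom fits without the incomplete library, counts of weeks 3 and 4 randomly thinned to the totals of the week 2 libraries, contrasts between neighbouring weeks, and scores of each library on the direction of the injury difference were added after the data were seen. The fit without the incomplete library was planned as 1 of those that leave out a library, and the choice to give it beside each comparison was made after the data were seen. Scores and positions used thinned log2 CPM over 2561 genes with a mean log2 CPM of at least 6, without the incomplete library.

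The edgeR steps were tested on simulated counts with the real library sizes and, for each gene, 1 mean and 1 dispersion over all 28 libraries. Of 100 genes changed 4-fold between injured and uninjured, 34 were recovered at week 2 (13576 genes tested), 50 at week 3 (13538 genes) and 58 at week 4 (13597 genes). Of 100 genes changed 2-fold, 5, 6 and 6 were recovered at weeks 2, 3 and 4. False calls numbered 1, 2 and 4. The simulation lacked group means and any spread particular to the week 2 libraries, so these numbers need not hold for the real data. Other splits of the real week 2 libraries gave a median of 299 calls.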

Results

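RNA was profiled from samples labelled as rat neural progenitor cells, in 7 groups of 4 libraries. Cells kept in culture were set against cells exposed to uninjured or injured spinal cord, each labelled 2, 3 or 4 weeks. Libraries held 5273204 to 6908508 counts in culture, 2886760 to 6824050 in uninjured week 3, 2605188 to 4449811 in uninjured week 4, 3147432 to 3614226 in injured week 3 and 3671962 to 4467448 in injured week 4. Week 2 libraries were far shallower, with 189626 to 426992 counts in the uninjured group and 84532 to 446331 in the injured group. They detected 11474 ± 1090 genes (SD, n = 4) and 10192 ± 1990 genes (SD, n = 4), against 17060 ± 211 (SD, n = 4) in culture. Injured week 3 replicate 3 detected 11544 genes, and the other 3 libraries of its group 15292 to 15583.

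**Figure D1:**
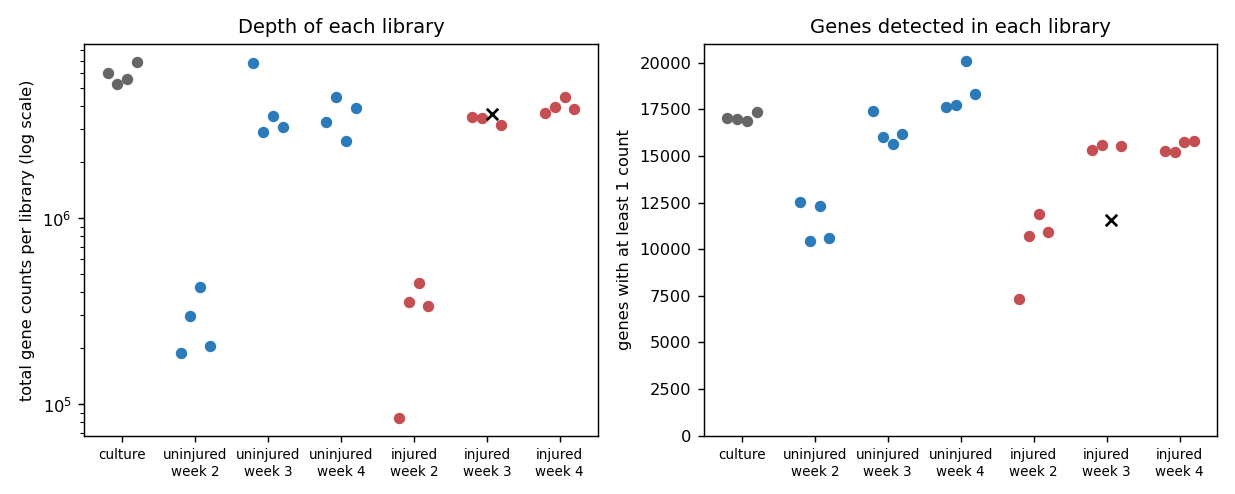
Left, total gene counts of each library on a log scale, and right, genes with at least 1 count, for the 7 groups of 4 libraries (points, 1 per library). The 8 week 2 libraries lie at or below 446331 counts and the other 20 at or above 2605188, and the cross marks injured week 3 replicate 3, which detected 11544 genes.

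The expression profiles of the uninjured groups labelled 3 and 4 weeks were close to one another and far from culture. Without injured week 3 replicate 3, the mean Spearman correlation across genes was 0.954 between uninjured weeks 3 and 4, 0.708 between culture and uninjured week 3, and 0.737 between culture and uninjured week 4. The injured groups labelled 3 and 4 weeks correlated better with culture than uninjured ones did, at 0.899 and 0.813. Injured week 3 was nearer to culture than to uninjured week 3 (0.711), but injured week 4 was nearer to uninjured week 4 (0.854) than to culture. At week 2 the means with culture were 0.582 for injured and 0.604 for uninjured exposure. Injured weeks 3 and 4 correlated at 0.880 with one another, and within groups the mean was 0.976 and 0.973. Both week 2 groups correlated better with uninjured than with injured week 4 libraries. The means were 0.761 and 0.675 for uninjured week 2, and 0.734 and 0.650 for injured week 2. Libraries within the week 2 groups, the shallowest, correlated at 0.663 and 0.614. The first 2 principal components of all 28 libraries held 26.4% and 17.8% of the variance. Injured week 3 replicate 3 lay at -242.5 on the second component, where the other 3 libraries of its group lay between -33.55 and -27.66. Injured week 2 replicate 1, the library with the fewest counts, lay at -211.6 and the others of its group between -0.2051 and 14.02.

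The comparison of injured with uninjured cord addresses how the RNA of the exposed samples differed with injury. The labels do not say whether the cells were separated from surrounding tissue, so a change in the cells cannot be told apart from RNA of that tissue. At week 4, 2396 of 13865 genes differed, 884 higher and 1512 lower after exposure to injured cord (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The count was 3895 without injured week 3 replicate 3, with 1723 higher and 2172 lower, and 6269 without the week 2 libraries as well, with 3227 higher and 3042 lower, a set chosen after the data were seen. Of the 2396, 819 were at least 2-fold higher and 1455 at least 2-fold lower. The files do not pair identifiers with gene names, so the genes with the largest changes are given by identifier. They were chosen on these week 4 values, so their p-values in other comparisons that use week 4 libraries are not free of that choice.

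ENSRNOG00000017333 rose at week 4 from 5.71 ± 6.29 CPM in uninjured to 1243 ± 134 CPM in injured libraries (SD, n = 4 each), a log2 fold change of 7.80 with a standard error of 0.71 (edgeR adjusted p = 5.5e-09). ENSRNOG00000008911 rose from 0.322 ± 0.381 to 53.6 ± 0.665 CPM (SD, n = 4 each), a log2 fold change of 7.33 with a standard error of 0.995 (edgeR adjusted p = 1.32e-05), from only 4 counts over the uninjured group. ENSRNOG00000002322 fell from 35.3 ± 10.3 CPM (SD, n = 4) to 0 counts in all 4 injured libraries. With a floor of 3 counts over the group this was at least 166-fold lower (edgeR adjusted p = 2.13e-08). ENSRNOG00000045811 fell from 170.6 ± 68.3 to 0.371 ± 0.540 CPM (SD, n = 4 each), a log2 fold change of -8.72 with a standard error of 0.75 (edgeR adjusted p = 1.92e-09), with 5 counts left over the injured group.

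At week 3, 5442 of 13865 genes differed, 2492 higher and 2950 lower in injured than in uninjured exposure (edgeR adjusted p under 0.05). There were 6570 without injured week 3 replicate 3, 2959 higher and 3611 lower. The balance turned with RLE factors on the same 27 libraries (3921 higher and 3137 lower, chosen after the data were seen) and, with all 28, with RLE factors (2827 and 2778), DESeq2 (4146 and 3313) and limma voom with quality weights (5157 and 4125). All 4 identifiers changed in the direction seen at week 4. ENSRNOG00000017333 had 374 ± 41.5 CPM in injured and 1.73 ± 1.29 CPM in uninjured libraries (SD, n = 4 each), a log2 fold change of 7.62 with a standard error of 0.72 (edgeR adjusted p = 2.57e-09). ENSRNOG00000045811 had 2.67 ± 2.10 CPM in injured and 174.8 ± 40.1 CPM in uninjured libraries (SD, n = 4 each), a log2 fold change of -5.95 with a standard error of 0.61 (edgeR adjusted p = 1.3e-08). ENSRNOG00000002322 had a log2 fold change of -5.50 with a standard error of 0.60 (edgeR adjusted p = 7.61e-08). Leaving out replicate 3 moved the log2 fold change of ENSRNOG00000045811 to -6.62 with a standard error of 0.53, and that of ENSRNOG00000002322 to -6.20 with a standard error of 0.61. ENSRNOG00000008911 had a log2 fold change of 6.18 with a standard error of 1.17 (edgeR adjusted p = 0.000188). Its injured week 3 mean of 7.65 ± 5.33 CPM (SD, n = 4) includes 0 counts in replicate 3, and without that library the log2 fold change was 6.49 with a standard error of 0.74.

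At week 2, 300 of 13865 genes passed the test, 186 of them lower in injured than in uninjured exposure (edgeR adjusted p under 0.05), and 481 passed without injured week 3 replicate 3. None of the 4 identifiers, which were chosen on week 4, was among them. Applied to week 2 itself, the naming rule without the symbol was met by 85 other genes, which are not printed. ENSRNOG00000017333 stood at 3.41 ± 5.18 CPM in injured and 23.3 ± 24.8 CPM in uninjured libraries (SD, n = 4 each; edgeR adjusted p = 0.159), from 6 and 22 counts. ENSRNOG00000045811 stood at 271.9 ± 98.5 CPM in injured and 206.1 ± 77.7 CPM in uninjured libraries (SD, n = 4 each; edgeR adjusted p = 0.759), from 366 and 233 counts. ENSRNOG00000002322 had an edgeR adjusted p of 0.41, from 46 and 18 counts, and ENSRNOG00000008911 had 0 counts in all 8 week 2 libraries. The week 2 calls depended on the fit and its gene filter. When only the 8 week 2 libraries were fitted, 4992 genes were tested and 0 called. Of these genes, 135 had an unadjusted p under 0.05, fewer than chance alone would give. DESeq2 gave 1059 calls. Of the 35 ways of splitting those 8 libraries, 18 gave at least 300 calls, the real one included.

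**Figure D2:**
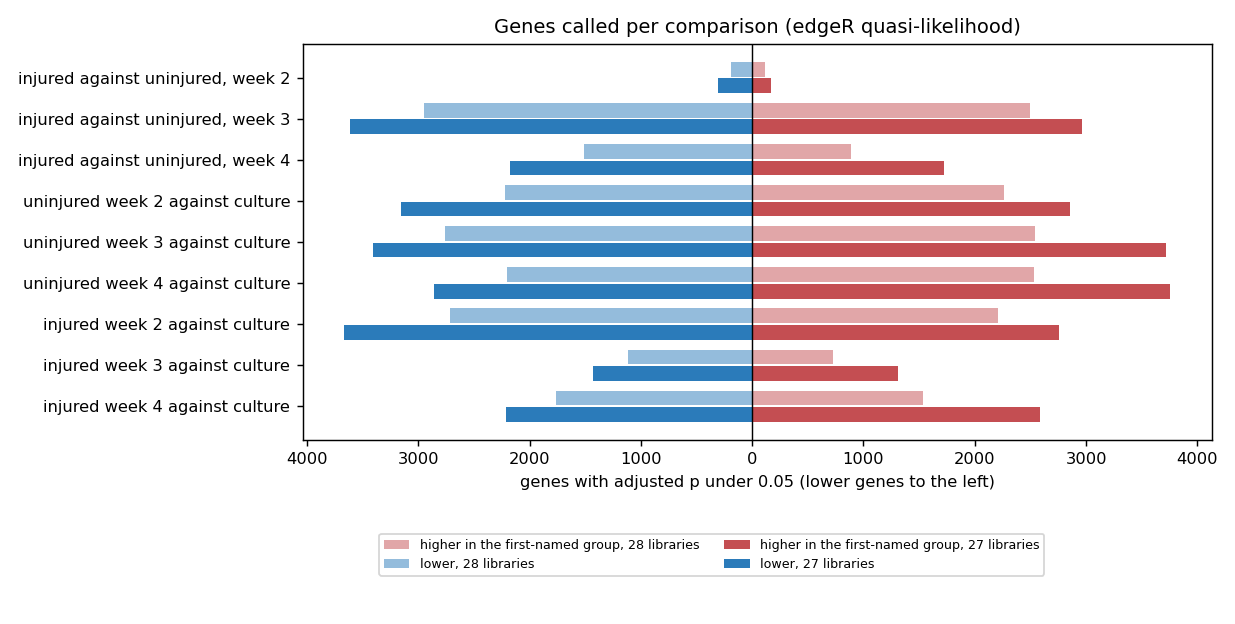
Genes with an edgeR adjusted p under 0.05, higher (bars to the right) or lower (bars to the left) in the group named first, with all 28 libraries (pale) and with the 27 that exclude injured week 3 replicate 3 (dark). Injured against uninjured gave 300, 5442 and 2396 genes at weeks 2, 3 and 4 with 28 libraries and 481, 6570 and 3895 with 27.

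The effect of injury differed between weeks for 3767 of 13865 genes (edgeR test with 2 degrees of freedom, adjusted p under 0.05), and for 5082 without injured week 3 replicate 3. Averaged over weeks, 4325 genes differed between injured and uninjured exposure, 1578 higher and 2747 lower, and 5398 without that library. Across the 13865 genes, the log2 fold changes of weeks 3 and 4, which share no library, correlated at a Pearson r of 0.672 and a Spearman rho of 0.613. The correlations of week 2 were -0.021 with week 3 and 0.01 with week 4 (Pearson). Only 4992 genes passed the filter when the week 2 libraries were fitted alone. Most week 2 fold changes thus rest on few counts, which pulls their correlations toward 0. Thinning weeks 3 and 4 to the week 2 totals, without injured week 3 replicate 3, left 8551 genes. The Pearson r was then 0.653 between weeks 3 and 4, and -0.035 and -0.011 for week 2 with weeks 3 and 4. Genes are not independent replicates, so no p is attached to these values. Weeks 3 and 4 shared 738 genes called higher, where independent lists would share 159, and 1124 called lower, where independent lists would share 322. Without injured week 3 replicate 3, 2803 genes were called in the same direction at both weeks. At week 2 their fold change in that direction had a median of -0.018 log2 units (quartiles -0.652 and 0.559), and 46.7% had the same sign. Low week 2 counts limit these values too.

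**Figure D3:**
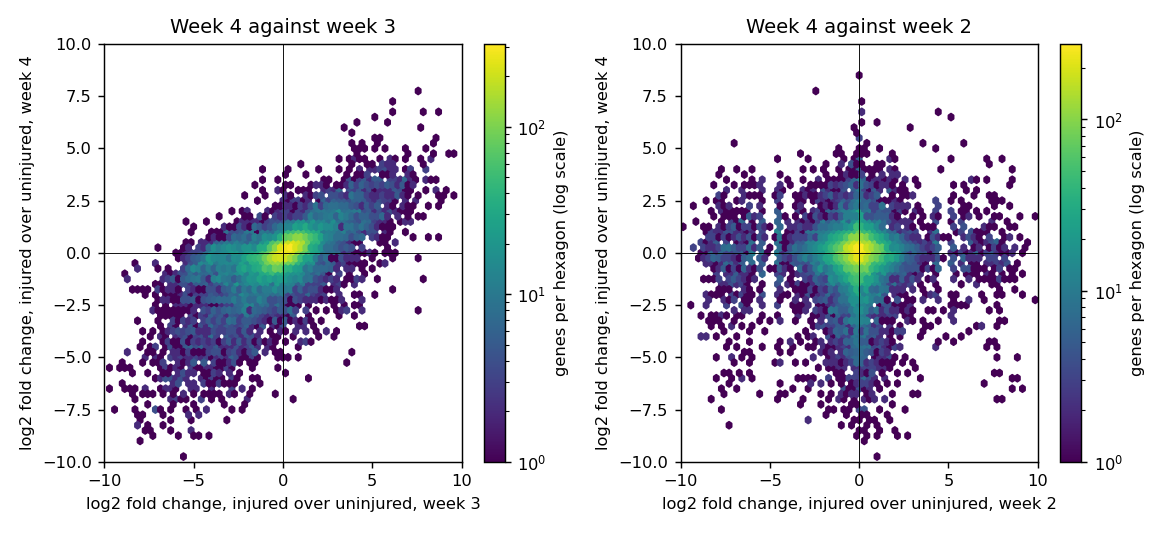
Log2 fold changes of injured over uninjured exposure for the 13865 genes tested in all 28 libraries, week 4 against week 3 (left) and week 4 against week 2 (right), with the number of genes in each hexagon on a log colour scale. The Pearson correlation across genes was 0.672 on the left and 0.01 on the right.

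Each library was then scored on the injured minus uninjured difference of the other weeks, with weeks 3 and 4 thinned to the week 2 totals, on a scale where 0 is the uninjured mean of its own week and 1 the full difference of the other weeks. This measure was chosen after the data were seen. Injured week 3 libraries scored 0.996 ± 0.029 (SD, n = 3) on the week 4 difference, and uninjured ones 0 ± 0.029 (SD, n = 4). The permutation p was 0.0286, two-sided, the smallest possible, and 0.0429 adjusted over the 3 weeks. Injured week 4 libraries scored 0.421 ± 0.027 (SD, n = 4) on the week 3 difference, and uninjured ones 0 ± 0.053 (SD, n = 4). The permutation p was again 0.0286, two-sided, the smallest possible, and 0.0429 adjusted. Both means rest on the same sum over genes of week 3 times week 4 differences, divided by the squared size of the difference scored on. They are thus not separate results, and their gap reflects only the larger size of the week 3 difference, noise included. Injured week 2 libraries scored 0.014 ± 0.093 (SD, n = 4) and uninjured ones 0 ± 0.073 (SD, n = 4, permutation p = 0.686, two-sided). The 0 point was set with the real labels and not recomputed for each arrangement, so these permutation p-values are approximate. The week 2 difference was 0.015 with a standard error of 0.059.

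**Figure D4:**
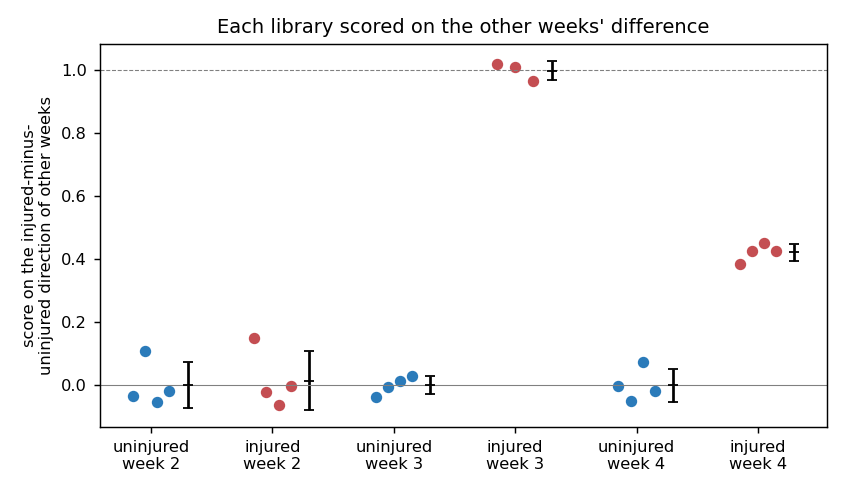
Score of each exposed library (points) on the injured minus uninjured difference of the other weeks, where 0 is the uninjured mean of its week and 1 the full difference, with mean and SD as bars beside the points. Injured libraries averaged 0.014 at week 2 (n = 4), 0.996 at week 3 (n = 3, without replicate 3) and 0.421 at week 4 (n = 4). The means of weeks 3 and 4 share 1 sum of products and differ only through the size of the difference they are divided by.

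Samples exposed to spinal cord were set against cells kept in culture. The exposed samples may hold RNA of surrounding cord tissue. A difference from culture therefore cannot be told apart from such RNA as a change in the cells. Averaged over the 6 exposed groups, 5021 of 13865 genes differed from culture, 1805 higher and 3216 lower (edgeR adjusted p under 0.05), and 6567 without injured week 3 replicate 3, 2643 higher and 3924 lower. ENSRNOG00000045811 rose in uninjured exposure from 0.320 ± 0.216 CPM in culture (SD, n = 4), by log2 fold changes of 9.14, 8.90 and 8.86 at weeks 2, 3 and 4 with standard errors of 0.74, 0.73 and 0.73 (edgeR adjusted p = 3.38e-10, 2.31e-10 and 3.2e-10). In injured exposure it was 9.54 with a standard error of 0.75 at week 2 and 2.95 with a standard error of 0.70 at week 3 (edgeR adjusted p = 1.87e-10 and 0.00392). At week 4 it was 0.14 with a standard error of 0.93 (edgeR adjusted p = 0.947). ENSRNOG00000017333 stood at 246.9 ± 51.5 CPM in culture (SD, n = 4) and fell in uninjured exposure by 5.33 on the log2 scale, with a standard error of 0.42 (edgeR adjusted p = 6.34e-11). In injured exposure it was below culture at week 2, with a log2 fold change of -5.79 and a standard error of 0.78 (edgeR adjusted p = 1.77e-06), and 0.60 with a standard error of 0.52 at week 3 (edgeR adjusted p = 0.575). In injured week 4 libraries it was above culture, with a log2 fold change of 2.33 and a standard error of 0.55 (edgeR adjusted p = 0.0017).

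Uninjured exposure differed from culture for 4483, 5305 and 4734 genes at weeks 2, 3 and 4, and for 6110 genes on average (2675 higher and 3435 lower). Injured exposure differed for 4925, 1838 and 3302 genes at weeks 2, 3 and 4, and for 3612 on average (1267 higher and 2345 lower). Without injured week 3 replicate 3 the uninjured counts were 6010, 7124, 6615 and 7716, and the injured counts were 6422, 2744, 4801 and 4936. With the log2 library total as a covariate, the averages were 1728 genes for all exposed groups, 2563 for uninjured and 1159 for injured exposure, of which 1050, 1613 and 678 were higher. By week they were 612, 4728 and 4011 for uninjured and 645, 1386 and 3025 for injured exposure at weeks 2, 3 and 4, so the largest falls were in the shallow week 2 libraries. Culture libraries held more counts than all exposed libraries but 1, uninjured week 3 replicate 1, so depth and exposure partly coincide.

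Time was compared between weeks within each condition. In uninjured exposure, 880 of 13865 genes differed among weeks 2, 3 and 4 (edgeR test with 2 degrees of freedom, adjusted p under 0.05), and in injured exposure 5535 did. The counts were 2368 and 7491 without injured week 3 replicate 3. Averaged over both conditions, 2798 genes differed between weeks 4 and 2, 1513 higher and 1285 lower at week 4, and 5122 without that library, 3580 higher and 1542 lower. ENSRNOG00000045811 was lower at week 4 than at week 2, by a log2 fold change of -4.84 with a standard error of 0.45 averaged over both conditions (edgeR adjusted p = 1.95e-08). Its uninjured levels were 206.1 ± 77.7 and 170.6 ± 68.3 CPM and its injured levels 271.9 ± 98.5 and 0.371 ± 0.540 CPM at weeks 2 and 4 (SD, n = 4 each). With weeks 3 and 4 thinned to the week 2 totals without injured week 3 replicate 3, chosen after the data were seen, 1426 of 8551 genes differed between weeks 4 and 2 (561 higher and 865 lower), 417 among the uninjured weeks and 3160 among the injured weeks. With the log2 library total as a covariate, which is nearly set by week, 10 genes differed between weeks 4 and 2, 2805 among the injured weeks and 0 among the uninjured weeks (1287 at an unadjusted p under 0.05; DESeq2 without the covariate, 2555). RLE factors gave 1105 higher and 1486 lower genes between weeks 4 and 2, a share of 42.6% higher against 54.1%. On the 27 libraries, a fit chosen after the data were seen, they gave 1693 higher and 2035 lower, so the balance between these weeks depended on scaling.

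Weeks 3 and 4 were sequenced to similar depth. Between them, 0 genes differed in uninjured exposure (edgeR, all 28 libraries; 1050 at an unadjusted p under 0.05), and 2242 differed in injured exposure, 1465 higher and 777 lower at week 4. Without injured week 3 replicate 3 the counts were 75 and 3078, and without the week 2 libraries as well they were 1619 and 5435. The injury effect itself differed between weeks 3 and 4 for 1801 genes, for 2674 without that library and for 4629 without the week 2 libraries as well (edgeR adjusted p under 0.05). These contrasts were added after the data were seen.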

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

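The tests of the incomplete library, of depth, of the week 2 scores and of week 2 labels were chosen after the results they bear on had been seen. The counts over other splits of the libraries were planned before their results were seen, except that of injured against uninjured at week 3. In 63 groups of 4 values, 16 had a library outside the spread of the others by Dixon's ratio, where chance gives about 3.2 for continuous values. In 6 of the 16 the other 3 libraries had equal values, which fixes the ratio at 1, so the excess over chance is partly set by construction.

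Injured week 3 replicate 3 lacked many genes that its 3 companions expressed. It detected 11544 genes against 15292 to 15583, and 2755 of 9636 genes with at least 20 expected counts were at 0, against 0 in each companion. Against low depth, 28.6% of such genes were at exactly 0 in this library of 3614226 counts. A wrong label or swap is argued against by the genes it did hold, over which its mean Spearman correlation was 0.955 with its own group, 0.116 above that with any other group. Genes were nearly all present or at 0, with 0.021% between 0 and 0.25 times the expected count. This would follow if part of the genes had been left out when this library was counted or tabulated. No biological explanation was tested. Expected counts were scaled to the full total of the library, so with many genes absent, those it held tended to stand above them. The limit of 0.25 is therefore laxer than it reads, and milder partial losses would be missed.

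The same library had the lowest log2 CPM of ENSRNOG00000008911 in its group, -0.593 against 3.266 to 3.703, and the highest of ENSRNOG00000002322, 1.133 against 0.335 to 0.382. The genes absent from it took 45.8% to 49.2% of the counts of its companions.

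The injury effect differed between weeks for 3767 genes. ENSRNOG00000017333, ENSRNOG00000002322 and ENSRNOG00000045811 were chosen for a large injury effect at week 4, and this test reuses those values, so their edgeR adjusted p of 8.19e-08, 2.1e-07 and 2.96e-08 are no evidence for a difference between weeks. Few genes differed at week 2. Against low totals alone as the cause, weeks 3 and 4 thinned to the week 2 totals gave 2818 and 1381 genes. The lower of these was still 8.80 times the 157 genes of week 2. Thinning removes counts at random and does not reproduce a smaller number of distinct molecules in the shallow libraries, which stays open. An injury difference of the week 3 and 4 kind hidden by spread is argued against by a mean week 2 difference of 0.015 with a standard error of 0.059, on a scale where that of weeks 3 and 4 is 1. That the week 2 libraries labelled injured were not exposed to injured cord cannot be told apart from a later onset of the difference, since the highest score of a week 2 injured library was 0.149 and no library of that week scored as injured. A change of the cells between weeks 2 and 3, and any batch shared by the shallow week 2 libraries, stay open as untested hypotheses.

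Other libraries outside the spread of their group are given as values. In culture replicate 1 the most abundant gene took 15.07% of counts (others 12.56% to 12.76%) and the 100 most abundant genes 40.44% (others 36.87% to 36.96%). Injured week 4 replicate 2 had 52.48% of counts in its 100 most abundant genes (others 41.58% to 43.19%). Uninjured week 3 replicate 1 held 6824050 counts (others 2886760 to 3522226). The number of genes at 0 with at least 20 expected counts was 1 in culture replicate 1, 3 in uninjured week 3 replicate 3, 1 in uninjured week 4 replicate 4 and 1 in injured week 4 replicate 4, against 0 in the others of each group. For ENSRNOG00000017333, culture replicate 4 had a log2 CPM of 8.341 (others 7.751 to 7.840), and for ENSRNOG00000045811, culture replicate 3 had -0.593 (others 0.07 to 0.186). For ENSRNOG00000008911, uninjured week 3 replicate 2 had -0.009 from a single count (others -0.593), and for ENSRNOG00000002322, uninjured week 3 replicate 3 had 4.759 (others 5.593 to 5.666).

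Chance as the source of the counts was tested on other splits of the libraries. At week 2, 18 of 35 splits into injured and uninjured gave as many genes as the real 300, with 485 in the highest of the others, so chance could not be excluded. The real split was the only 1 of 35 to reach its count at week 3 (5442 genes, highest other 257) and week 4 (2396 genes, highest other 0). So it was for each exposed group against culture, again 1 of 35 splits, the smallest share possible. The real and highest other counts were 4483 and 227, 5305 and 1, and 4734 and 0 for uninjured weeks 2, 3 and 4, and 4925 and 586, 1838 and 18, and 3302 and 0 for injured weeks 2, 3 and 4. These counts argue against a random split of these libraries as their source. They cannot exclude a chance difference between animals, cultures or batches, which the samples of a group may share. For the week 2 groups against culture, the real split also coincides with low depth. For the 8 wider comparisons 60 splits were used, and again only 1, the real one, reached its count. For the difference between weeks, these splits shuffled injured and uninjured labels within weeks. That removes any injury effect, also one equal at all weeks, so they cannot test whether the effect differs between weeks. For the averages against culture, labels were shuffled over all the groups compared. That mixes weeks, and for all exposed groups also injury, into each group and raises the spread within groups. Low counts in those splits are thus partly set by construction and do not single out exposure against culture. The real and highest other counts were 4325 and 1175 for the injury average, 3767 and 3184 for its difference between weeks, 5021 and 783 for all exposed groups against culture, 6110 and 34 for uninjured against culture, 3612 and 597 for injured against culture, 2798 and 1473 for week 4 against week 2, 880 and 254 for the uninjured weeks, and 5535 and 987 for the injured weeks.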

How the results depend on the processing

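Left-out sets of more than 1 library, thinning, and the RLE and voom fits without injured week 3 replicate 3 were chosen after the data were seen; the other settings were planned. Counts of all 17 comparisons stayed within 1.5 times under RLE factors, upper quartile factors and a filter of at least 1 CPM in at least 4 libraries; that filter, planned as stricter, kept more genes (15782), so none stricter than filterByExpr was run. For the 4 identifiers, 946 results kept direction and side of the threshold, 15 came to pass it, 3 no longer passed it (all with the library total as covariate) and none reversed. The alternative without mitochondrial and ribosomal RNA genes and the 5 alternatives for gene list tests were not run, since identifiers had no symbols. No paired analysis was possible because replicate numbers follow the order of deposition. Depth limits all week 2 results, and the cause of a change was not tested except where stated.

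Leaving out 1 library at a time gave 214 to 481 genes for injured against uninjured at week 2, 4730 to 6570 at week 3, 1940 to 3895 at week 4, 4090 to 5398 on average and 3334 to 5082 for the difference between weeks. The ranges were 3806 to 6567 for exposed, 5038 to 7716 for uninjured and 2731 to 4936 for injured against culture, 3950 to 6010, 4505 to 7124 and 4023 to 6615 for uninjured weeks 2, 3 and 4, 4228 to 6422, 1400 to 2744 and 2740 to 4801 for injured weeks 2, 3 and 4, 2504 to 5122 for week 4 against week 2, 620 to 2368 for the uninjured weeks and 5075 to 7491 for the injured weeks. The highest value came in each case without injured week 3 replicate 3, where the common dispersion was 0.0754 instead of 0.207. The other 2 libraries that moved a count by over 1.5 times were of injured week 2. Without its replicate 1 the uninjured weeks gave 1540 genes, and without its replicate 3 the week 2 comparison gave 479.

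No low count filter gave 96 genes for the week 2 comparison and 1448 for the uninjured weeks. The log2 library total as covariate gave 1728 for exposed, 2563 for uninjured and 1159 for injured against culture, 612 and 645 for uninjured and injured week 2 against culture, 10 for week 4 against week 2, 0 for the uninjured weeks (1287 at an unadjusted p under 0.05) and 2805 for the injured weeks; the covariate nearly separates week 2 from the rest by construction. A test against a 1.5-fold change gave 31 higher and 70 lower genes for week 2 (1.0e+02 in all), 2631 for the injury average and 1567 for week 4 against week 2. Fits of the compared groups only gave 0 for week 2, with 135 of 4992 genes at an unadjusted p under 0.05. They gave 4903 for week 4 and 2794 for the injured weeks. Against culture they gave 9124 and 8931 for uninjured weeks 3 and 4, and 3679 and 7190 for injured weeks 3 and 4.

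Voom with quality weights, which gave injured week 3 replicate 3 a weight of 0.00668, gave 0 for week 2. There, 585 of 13865 genes had an unadjusted p under 0.05, fewer than chance alone would give. It gave 9282 for week 3, 6330 for week 4 and 2338 for the difference between weeks. Against culture it gave 9591 for exposed, 9598 for uninjured and 7099 for injured exposure. By week against culture it gave 10309 and 9793 for uninjured weeks 3 and 4, and 6295 and 8917 for injured weeks 3 and 4. DESeq2 gave 1059 for week 2, 4150 for week 4, 6036 for the difference between weeks, 3555 and 5025 for injured weeks 3 and 4 against culture and 2555 for the uninjured weeks.

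Without injured week 3 replicate 3, counts moved to 481 for week 2, 3895 for week 4, 5122 for week 4 against week 2 and 2368 for the uninjured weeks. Without injured week 2 replicate 1 as well they were 622, 4273, 4268 and 2426, with 3012 and 5161 for injured weeks 3 and 4 against culture. RLE factors without the incomplete library gave 491 for week 2, 3920 for week 4 and 1818 for the uninjured weeks. Voom without it gave 3916 for week 4, 7544 for exposed and 5765 for injured against culture, 2804 for injured week 3 against culture, 6788 for week 4 against week 2 and 3077 for the uninjured weeks. Without it and all week 2 libraries, week 3 gave 8615 and week 4 6269, uninjured weeks 3 and 4 against culture 9237 and 8818, and injured weeks 3 and 4 against culture 5046 and 7112. Thinning gave 157, 2818 and 1381 for weeks 2, 3 and 4, 2699 for the average, 2328 for the difference between weeks, 1110 for injured week 3 against culture, 1426 for week 4 against week 2, 417 for the uninjured weeks and 3160 for the injured weeks; fewer counts and genes (8551) entered.

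Another scaling moved the share of higher genes by over 10 points for week 4 against week 2, to 42.6% with RLE factors (1105 of 2591) from 54.1%. Without the incomplete library, RLE factors moved it to 45.4% (1693 of 3728) from 69.9%, and for injured against uninjured at week 3 to 55.6% (3921 of 7058) from 2959 of 6570. The median log2 fold change over all genes moved by over 0.1 under another scaling in several comparisons. With 28 libraries it went from -0.23 to -0.04 with RLE and -0.03 with upper quartile factors for uninjured week 2 against culture. With 27 libraries RLE factors moved it from 0.39 to 0.07 for week 4 against week 2, and from 0.01 to 0.26 for injured against uninjured at week 3. Small changes in these comparisons are relative to such shifts.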

Other observations

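Exposed libraries were placed between the uninjured profile of their week label (0) and the culture profile (1), over thinned log2 CPM, a measure chosen after the data were seen. Injured week 3 libraries stood at 0.859 ± 0.028 (SD, n = 3) and uninjured ones at -0.001 ± 0.048 (SD, n = 4). The permutation p was 0.0286, two-sided, the smallest possible, and 0.0381 adjusted over 4 tests. Injured week 4 libraries stood at 0.332 ± 0.037 (SD, n = 4), against -0.003 ± 0.083 for uninjured ones (SD, n = 4). The permutation p was again 0.0286, two-sided, the smallest possible, and 0.0381 adjusted. The positions of injured weeks 3 and 4 differed from one another (permutation p = 0.0286, two-sided, the smallest possible, 0.0381 adjusted). Each week has its own line from uninjured to culture, so these positions lie on different scales. A change of the uninjured libraries between weeks would move them too. Injured week 2 libraries stood at -0.020 ± 0.018 (SD, n = 4) and uninjured ones at -0.001 ± 0.063 (SD, n = 4, permutation p = 0.600, two-sided). The 0 and 1 points were set with the real labels and not recomputed for each arrangement, so these permutation p-values are approximate.

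A candidate explanation for the intermediate position is a mixture of culture-like and uninjured-like RNA in the injured libraries, which would leave hardly any gene beyond both. The test was written before its result was seen. At week 3, 615 genes lay at least 2-fold above and 673 at least 2-fold below both uninjured and culture (edgeR adjusted p under 0.05 against each), 9.02% of the 14282 tested without injured week 3 replicate 3. At week 4, 439 lay above and 642 below, 7.57%. Of the genes called against both uninjured and culture, 578 at week 3 and 580 at week 4 lay between them, at any fold. These were fewer than the 1288 and 1081 beyond both. A gene between the profiles but near culture or near uninjured is hard to call against both, so it was not counted. The comparison of these counts therefore does not show what share of genes lay between. The genes beyond both argue against a mixture of these profiles alone. A mixture with a further change in the cells or with RNA of other cells stays open as a hypothesis.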
